A study of Arabidopsis thaliana with 4 samples.

How the data were processed

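Ribosome profiling (Ribo-seq) libraries were made from whole Arabidopsis thaliana seedlings aged 6 days, with 2 libraries of wild type and 2 of ClpD overexpression line 5. Per the labels' protocols, frozen tissue was ground and lysed in a buffer with cycloheximide, which holds ribosomes on the mRNA, the lysate was digested with RNase I and DNase I to leave footprints, and libraries were sequenced on an Illumina instrument. How ribosomes were isolated, how footprints were sized and whether ribosomal RNA was removed are not given in the sources used here. Ribosome runoff, nuclease digestion and footprint recovery can differ between lysates, and chloroplast and mitochondrial ribosomes are not the target of cycloheximide, so organelle footprints may be held less firmly than cytosolic ones.

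The authors deposited 1 table for the whole series. Per the file headers it holds a count and an FPKM value per gene and library, the authors' mean FPKM of each group, a log2 fold change, a p-value and an FDR. Per the submitters' processing notes the tools were fastp, Bowtie2, STAR, RSEM and DESeq2 and the build was TAIR10, with no versions or roles. The counts as deposited are whole numbers with a different total in each library; RSEM gives expected counts, so they may have been rounded by the authors. The authors' FPKM values divide the counts by gene length and library total and were used only through the authors' comparison columns. The authors' log2 fold change equals the log2 ratio of their mean FPKM values within rounding. Which test gave the authors' p-value, whether counting used strand, and whether it was limited to coding sequence are not given in the sources used here. Reads of near-identical gene copies and of overlapping or antisense genes may therefore be divided in a way that was not tested.

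The table lists 27554 genes with an identifier. A further 5 rows without one had counts identical to 5 plastid genes of the inverted repeat and were left out of library sizes and tests; they held from 0.0145% to 0.0340% of the counts of a library. Names were taken from the RefSeq table of assembly TAIR10.1, in which 27444 of the 27554 identifiers were found, and otherwise from the deposited table. Because that assembly differs in name from the authors' build, no coordinates are printed.

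Total counts ranged from 27260818 to 42291527 per library. A floor of 3 counts corresponds to 0.0709 to 0.110 CPM. Where a library of a group had 3 counts or fewer, the ratio of counts summed over each group and scaled by effective library size is given with its exact binomial 95% counting interval in place of a fitted fold change, and the ratio with a library left out where that moved it by more than 1.5 times. TMM factors were 0.953 and 0.889 for WT and 1.07 and 1.10 for line 5. Counts of the 2 libraries of a group differed by more than sampling noise (chi-square per degree of freedom 39.0 for WT and 25.7 for line 5), so each library was counted as 1 sample.

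Differential footprint counts were tested with edgeR 4.0.16 (R 4.3.3): genes kept by filterByExpr with a minimum count of 10, TMM normalization, a quasi-likelihood fit on group alone, a two-sided test and Benjamini-Hochberg adjustment over the 18737 genes kept, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Levels are TMM-scaled CPM, the count of a gene scaled by the effective library size. Common dispersion was 0.0262. Lists of genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The p-values were adjusted over the 22 planned lists tested, and those of lists put together after the data were seen over those lists alone. Camera with a correlation estimated from the residuals and fry were alternatives. With the estimated correlation none of the 22 lists was called, the lowest adjusted p being 0.443. The residuals of only 4 libraries leave few degrees of freedom for that estimate, so camera then has little power and a missing call decides little. Fry asks whether a list moved at all, camera whether it moved relative to the other genes. Shares of plastid-encoded counts were compared by a two-sided exact permutation test.

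The 20 lists of nuclear genes (350 members), the plastid-encoded and mitochondria-encoded lists, the tests, the alternatives and the rule for named genes were written before the data were examined. The rule names ClpD, the 10 largest increases and the 10 largest decreases among called genes whose libraries do not overlap between groups and whose mean level is at least 5 CPM, and up to 4 members of each list with the smallest p. Other genes are named where a count was 5 or fewer or where a member was singled out after its values were seen: AOX1A, NAC053, NAC2, RBCS1A, LHB1B1, PORA, GUN1, CAT1, ELIP2, BIP3, BZIP60, AT1G59860, the second ycf1 copy and those of the closing section. In the lists, 2 members whose symbol belongs to another gene in the reference were left out. A further 2 planned lists of ribosomal proteins depended on gene descriptions that the reference table did not hold and were left out, as planned for that case.

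The procedure was tested on simulated counts for the 18737 genes kept, drawn from the means, dispersions and library sizes of these samples. Of these genes, 18586 passed the filter again. In the simulated comparison of line 5 against WT, 50 genes each were raised 2-fold, lowered 2-fold, raised 4-fold and lowered 4-fold. All were drawn from genes with a mean of at least 5 CPM, so recovery of genes with lower levels was not tested. Called were 36 (72%) of those raised 2-fold, 30 (60%) of those lowered 2-fold and 100% of those changed 4-fold in either direction. A further 29 unchanged genes were called, a larger share of all calls than the adjusted p threshold aims for. The edgeR calls in the real samples may therefore also hold more false ones than that threshold aims for. Of 24 simulated lists without a shift, 0 were called, and the shifted list, also drawn from genes of at least 5 CPM, was called. Simulated genes were drawn independently, so these lists could not show whether the preset correlation of 0.01 is high enough for genes that move together.

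Alternatives were DESeq2 1.42.0 (Wald test, its own size factors and filtering), RLE and upper-quartile normalization, no filter, a stricter filter (5 CPM in 2 libraries), library sizes without organelle genes and ClpD, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, and an added absolute log2 fold change of 1. DESeq2 gave no adjusted p for 4085 genes. With 1 library left out, the lone library of its group is assumed to vary like the other group.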

Results

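Ribosome footprints, the short mRNA pieces that a translating ribosome shields from nuclease, were counted per gene in whole Arabidopsis thaliana seedlings aged 6 days. The seedlings were wild type (WT, n = 2 libraries) or belonged to line 5, a line that constitutively overexpresses ClpD (n = 2 libraries). ClpD, listed in the reference as ERD1, is a nucleus-encoded Clp ATPase of the chloroplast stroma that is made in the cytosol as a precursor. Per the series' title and design text, the submitters asked how seedlings in which they saw the ClpD precursor accumulate respond, and whether the response resembles that to heat shock; precursor proteins and their import were not measured in the data used here. The total count was 29772406 in WT replicate 1 and 27260818 in WT replicate 2. It was 42291527 and 38990360 in replicates 1 and 2 of line 5. Footprint counts follow both mRNA level and ribosome occupancy, and the matching RNA-seq was not analysed here, so no translational efficiency is given. Line 5 is the only overexpression line here, so effects of ClpD overexpression cannot be told apart from other differences of that line. Nothing in the labels says whether the libraries of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera with its preset correlation compares list members with the other genes tested and takes genes, not libraries, as its units. Its p-values therefore do not measure that spread, and a call kept with 1 library left out does not measure agreement between libraries.

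The overexpressed gene was higher in line 5, as its label says. ClpD (ERD1, AT5G51070) had 171 ± 5.40 CPM (SD, n = 2) in WT and 3207 ± 134 CPM (SD, n = 2) in line 5, an 18.8-fold increase (log2 fold change 4.23, SE 0.128, edgeR quasi-likelihood test, adjusted p = 0.00126). The authors' deposited table gives a log2 fold change of 4.47 for it. Of 18737 genes tested, 1260 were called higher and 1633 lower in line 5 by edgeR with Benjamini-Hochberg adjustment. Of these, 599 rose and 905 fell by at least 1 on the log2 scale. DESeq2 called 1512 higher and 2162 lower, of which 1171 and 1595 were also called by edgeR. The authors' deposited table lists 1420 higher and 2067 lower with its FDR under 0.05, a threshold chosen here. With an added absolute log2 fold change of at least 1 it lists 978 higher and 762 lower, the opposite balance to the 599 and 905 of edgeR. The authors' fold changes are ratios of mean FPKM. Far fewer of the 2893 edgeR calls remained with either line 5 library left out, where only the WT pair gives a spread. That pair differed more than the line 5 pair (SD of the log2 CPM difference across genes 0.512 against 0.344). Effect sizes did not fall alike: without replicate 1 or 2 of line 5 the proteasome median log2 fold change was 0.36 and 0.38, against 0.36. The photosynthesis median was -0.58 and -0.57, against -0.56. That of the heat shock regulators was 0.80 and 0.43, against 0.73. Log-CPM values correlated across genes at r = 0.980 within WT, 0.990 within line 5 and 0.936 to 0.957 between the groups, where genes are not independent replicates.

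Cytosolic heat shock proteins rose together in line 5. All 11 tested cytosolic small heat shock proteins, chaperones that hold unfolded proteins, rose, with a median log2 fold change of 3.96, and 11 were higher adjusted over the list alone (limma's camera, adjusted p = 3.54e-11; adjusted p = 0.443 with an estimated correlation). HSP17.6A (AT5G12030) went from 4.51 and 6.11 CPM in the WT libraries to 291 and 216 CPM in line 5, a 47.9-fold increase (edgeR, adjusted p = 0.00293). AT1G53540 rose 52.4-fold, AT2G29500 20.0-fold and AT1G07400 15.6-fold, the last sharing near-identical sequence with AT1G59860, so that its reads may be split. Of 20 tested cytosolic HSP70, HSP90, HSP101 and co-chaperone genes, 17 rose and 0 fell, and 20 were higher adjusted over the list alone (median log2 fold change 1.62; camera, adjusted p = 2.50e-12; adjusted p = 0.443 with an estimated correlation). The disaggregase HSP101 (AT1G74310) rose 12.2-fold (log2 fold change 3.61, SE 0.113), Hsp70b (AT1G16030) 18.2-fold, the HSP70-HSP90 linker Hop3 (AT4G12400) 7.63-fold and the nucleotide exchange factor Fes1A (AT3G09350) 7.35-fold. Among 15 tested heat shock factors and heat-induced regulators, 4 rose and 0 fell, and 8 were higher adjusted over the list alone (median log2 fold change 0.73; camera, adjusted p = 0.00368; adjusted p = 0.443 with an estimated correlation). These were HSFA2 (AT2G26150, log2 fold change 3.10, SE 0.378), HSFA7A (AT3G51910, 2.65, SE 0.344), the coactivator MBF1C (AT3G24500, 1.83, SE 0.284) and HSA32 (AT4G21320, 1.81, SE 0.365), with HSFA2 at 3.86 without WT replicate 1. With replicate 1 or replicate 2 of line 5 left out, edgeR called 6 and 7 of the small heat shock proteins, 3 and 3 of the HSP70, HSP90 and HSP101 list, and 0 and 0 of the regulators, while camera called the lists in each case. The regulator list missed the threshold with fry (adjusted p = 0.0507).

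**Figure D1:**
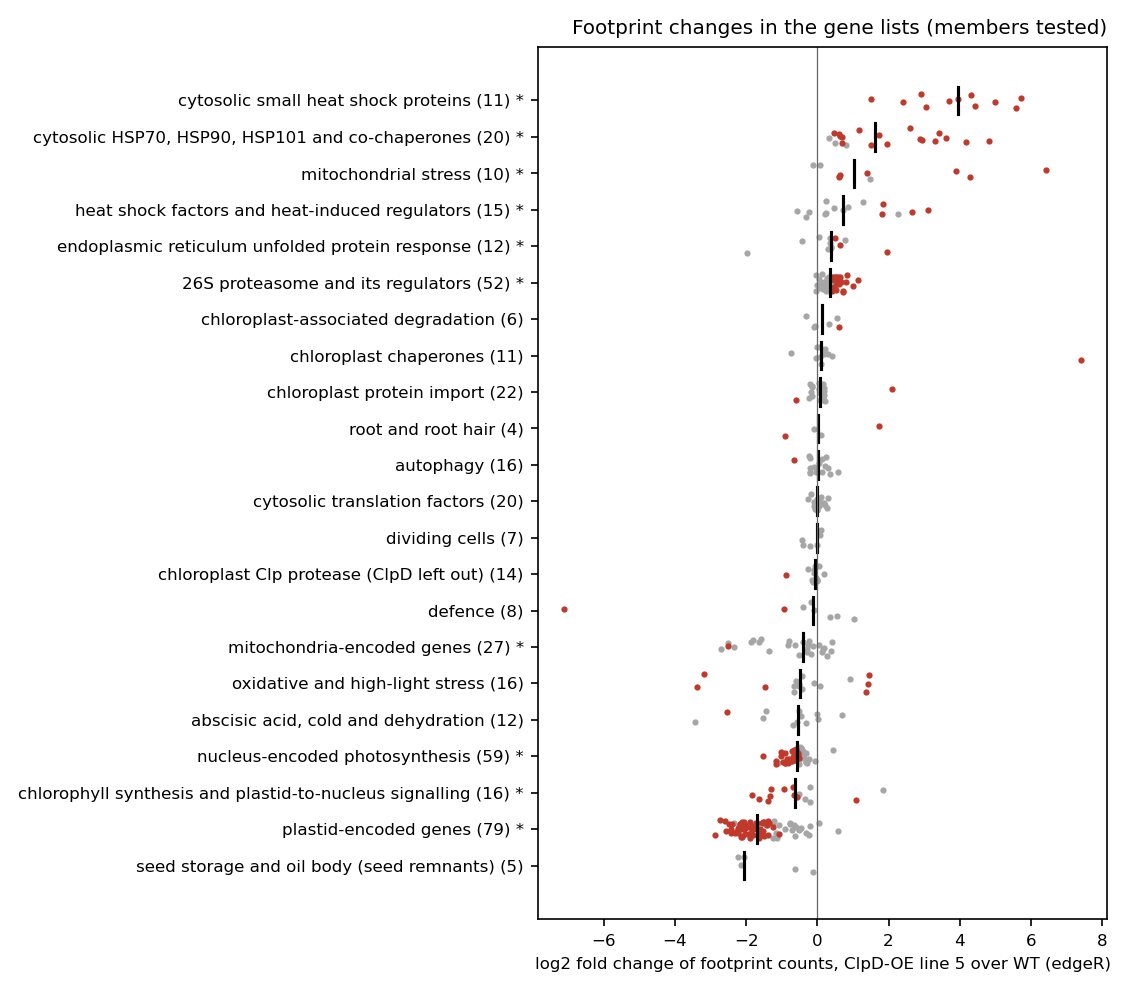
Log2 fold change of footprint counts in ClpD-OE line 5 over WT (x axis, edgeR, 2 libraries per group) for each tested member (points) of the 22 gene lists (y axis, number tested in parentheses), with red points for genes past an adjusted p of 0.05, grey points for the others and a black bar at the list median. Asterisks mark the 10 lists called by camera with its preset correlation, with medians from 3.96 for the cytosolic small heat shock proteins to -1.69 for the plastid-encoded genes; 0 lists were called with an estimated correlation.

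Mitochondrial stress genes and some endoplasmic reticulum chaperones were also higher in line 5. Of 10 tested mitochondrial stress genes, 6 rose and 0 fell, and 8 were higher adjusted over the list alone (median log2 fold change 1.02; camera, adjusted p = 2.68e-05; adjusted p = 0.443 with an estimated correlation). The small heat shock protein HSP23.6-MITO (AT4G25200) rose 85.8-fold, from 1.23 and 1.07 CPM to 101 and 97.9 CPM (edgeR, adjusted p = 0.000700). AT5G51440, another HSP20-like chaperone, rose 19.4-fold, AT2G21640, annotated as an oxidative stress marker, 14.9-fold and the mitochondrial HSP70 MTHSC70-2 (AT5G09590) 2.63-fold. AOX1A, the alternative oxidase that marks mitochondrial dysfunction, had a log2 fold change of 0.09 (SE 0.308) and was not called. Of 12 tested genes of the endoplasmic reticulum unfolded protein response, 3 rose and 0 fell, and 9 were higher and 1 lower adjusted over the list alone (median log2 fold change 0.37; camera, adjusted p = 0.0180; adjusted p = 0.443 with an estimated correlation). These 3 were the J-domain protein ATERDJ3A (AT3G08970, log2 fold change 1.96, SE 0.177), BIP1 (AT5G28540, 0.62, SE 0.0985) and CNX1 (AT5G61790, 0.49, SE 0.0997), while PDIL1-1 had 0.77 (SE 0.204) and was not called. The gene lower adjusted over the list alone was the transcription factor BZIP60 (AT1G42990, -0.42, SE 0.129), and BIP3 (AT1G09080), the member with the lowest value, had 15 and 27 counts in WT and 3 and 15 in line 5, a WT over line 5 ratio of 3.92 (95% counting interval 2.21 to 7.23), and was not called. That ratio was 12.1 without replicate 2 of line 5, 2.28 without replicate 1 of line 5 and 2.59 without WT replicate 2. Without replicate 1 or 2 of line 5, edgeR called 3 and 3 of the mitochondrial stress genes and 0 and 0 of the endoplasmic reticulum genes. The endoplasmic reticulum list lost its camera call without WT replicate 1 (adjusted p = 0.0552) and without replicate 1 of line 5 (adjusted p = 0.0571).

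Inside the chloroplast, most chaperones, proteases and import components were not called. Of 11 tested chloroplast chaperones, 1 rose, adjusted over the list alone also 1, and 0 fell (median log2 fold change 0.11; camera, adjusted p = 0.320). This was the small heat shock protein HSP21 (AT4G27670), with 3 and 2 counts in the WT libraries and 1073 and 421 in line 5, a ratio of 178 over the summed libraries (95% counting interval 76.1 to 549; edgeR, adjusted p = 0.0148), and of 103 without replicate 1 of line 5. CLPB3 had a log2 fold change of -0.73 (SE 0.202), CPN60A 0.30 (SE 0.133) and Cpn60beta2 0.42 (SE 0.210), none of them called. Of 14 tested Clp protease subunits other than ClpD, 1 fell and 0 rose, and adjusted over the list alone the counts were the same (camera, adjusted p = 0.408). It was the adaptor AT1G68660, listed as CLPS1, with a log2 fold change of -0.87 (SE 0.155), and HSP93-III (ClpC2) had 0.18 (SE 0.0986). Of 22 tested import genes, 1 rose and 1 fell, with 1 higher and 0 lower adjusted over the list alone (camera, adjusted p = 0.549). Tic20-IV (AT4G03320), a paralog of the inner envelope translocon channel, rose 4.28-fold (SE of the log2 fold change 0.208), TIC55-II (AT2G24820) fell by 0.61 on the log2 scale (SE 0.129), and TIC110 had 0.23 (SE 0.0951). Of 6 tested genes of chloroplast-associated degradation, 1 rose, also 1 adjusted over the list alone, and 0 fell (camera, adjusted p = 0.549): the ATPase CDC48 (AT3G09840, log2 fold change 0.60, SE 0.112). HSP21 kept its edgeR call without replicate 1 or 2 of line 5, and AT1G68660, Tic20-IV, TIC55-II and CDC48 did not; of the degradation genes edgeR called 2 without WT replicate 1 and 0 without WT replicate 2, where CDC48 had an adjusted p of 0.0528. The chloroplast chaperone list was called by camera without replicate 2 of line 5 (adjusted p = 0.0248).

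The proteasome list was higher in line 5 by a smaller median than the heat shock lists, and 32 of its 52 genes were not called. Of 52 tested genes of the 26S proteasome and its regulators, 20 rose and 0 fell, and 33 were higher adjusted over the list alone (median log2 fold change 0.36; camera, adjusted p = 1.49e-09; adjusted p = 0.443 with an estimated correlation). The regulatory particle genes MEE34 (AT3G11270, listed as RPN8B) rose 2.21-fold, AT5G20000 (RPT6B) 2.01-fold and RPT5B (AT1G09100) 1.77-fold, and the core particle gene PAA2 (AT2G05840) 1.65-fold. Each has a close paralog in the genome, so reads may be split between copies. The proteasome gene activators NAC053 and NAC2 (NAC78) had log2 fold changes of 0.09 and -0.01 and were not called. EdgeR called 0 and 0 of the 52 genes without replicate 1 or 2 of line 5, while camera called the list in each case.

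Nuclear genes for photosynthesis and chlorophyll synthesis fell in line 5. Of 59 tested nucleus-encoded photosynthesis genes, 31 fell and 0 rose, and 49 were lower adjusted over the list alone (median log2 fold change -0.56; camera, adjusted p = 2.44e-15; adjusted p = 0.443 with an estimated correlation). The Rubisco small subunit gene RBCS2B (AT5G38420) fell by 1.53 on the log2 scale (SE 0.172), and the light-harvesting genes LHCB2.1 (AT2G05100), LHCB2.2 (AT2G05070) and CAB2 (AT1G29920) fell by 1.17, 1.16 and 1.03. Members of these families are nearly identical in sequence, and RBCS1A, with a log2 fold change of -0.30, and LHB1B1, with -0.07, were not called. Of 16 tested genes of chlorophyll synthesis and plastid-to-nucleus signalling, 9 fell and 1 rose, and 12 were lower and 2 higher adjusted over the list alone (median log2 fold change -0.62; camera, adjusted p = 0.000116; adjusted p = 0.443 with an estimated correlation). The transcription factors GLK2 (AT5G44190) and GPRI1 (AT2G20570, GLK1), activators of photosynthesis genes, fell by 1.83 (SE 0.113) and 1.63 (SE 0.127) on the log2 scale. HEMA1 (AT1G58290), at the first committed step of tetrapyrrole synthesis, fell by 0.95 and CH1 (AT1G44446, chlorophyllide a oxygenase) by 1.31. The gene that rose was PORA (AT5G54190), a protochlorophyllide oxidoreductase of dark-grown seedlings, 2.14-fold (SE of the log2 fold change 0.248), while GUN1 had -0.22 (SE 0.0949) and was not called. Clock genes moved with these lists: 10 of 11 tested dawn-phased genes, a list put together after the data were seen, fell and EPR1 rose (median log2 fold change -1.59; camera, adjusted p = 3.17e-05; adjusted p = 0.342 with an estimated correlation), and 1 and 0 of them were lower by edgeR without replicate 1 or 2 of line 5. In the same fits edgeR called 0 and 0 of the members of the photosynthesis and the chlorophyll lists, and without WT replicate 2 it called 17 of the photosynthesis genes lower, while camera called both lists in each case.

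**Figure D2:**
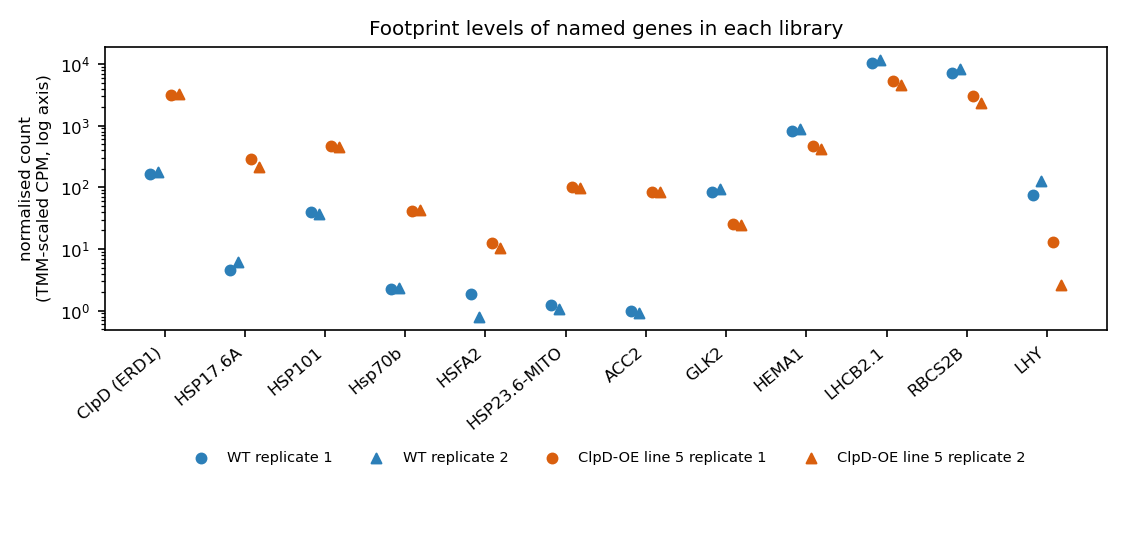
Normalised count (TMM-scaled CPM, log axis) of 12 named genes (x axis) in each of the 4 libraries, with WT in blue, ClpD-OE line 5 in orange, circles for replicate 1 and triangles for replicate 2. ClpD lies near 171 CPM in WT and 3207 CPM in line 5, and LHY lies at 75.6 and 127 CPM in WT against 12.9 and 2.57 CPM in line 5.

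Footprints on plastid-encoded genes were fewer in line 5. They made up 1.25% (95% exact binomial interval 1.24 to 1.25) and 2.32% (2.31 to 2.32) of the counts in WT replicates 1 and 2 and 0.503% (0.501 to 0.506) and 0.597% (0.594 to 0.599) in line 5. These intervals and the ratios given for genes with few counts cover counting error only. The mean was 1.78% ± 0.756 (SD, n = 2) in WT and 0.550% ± 0.0659 (SD, n = 2) in line 5 (two-sided exact permutation test, p = 0.333, the smallest p that 2 against 2 libraries allow). The difference of -1.23 percentage points was -0.697 without WT replicate 2. Of 79 tested plastid-encoded genes, 56 fell and 0 rose, and 67 were lower adjusted over the list alone (median log2 fold change -1.69; camera, adjusted p = 5.59e-19; adjusted p = 0.651 with an estimated correlation). The photosystem I assembly gene ycf4 fell by 1.60 on the log2 scale (SE 0.135), the ATP synthase gene atpF by 1.62 (SE 0.160), the ribosomal gene rps14 by 1.39 (SE 0.144) and ycf1 (ATCG01130) by 1.09 (SE 0.115), while the second ycf1 copy listed had a log2 fold change of -0.90 (SE 0.257) and was not called. Of 27 tested mitochondria-encoded genes, 1 fell (atp1, log2 fold change -2.50, SE 0.570, -3.13 without WT replicate 1 and -1.40 without WT replicate 2) and 0 rose, with 0 and 0 adjusted over the list alone (median log2 fold change -0.40; camera, adjusted p = 0.0287; adjusted p = 0.832 with an estimated correlation). Their share was 0.0488% ± 0.0109 (SD, n = 2) in WT and 0.0459% ± 0.00315 (SD, n = 2) in line 5 (two-sided exact permutation test, p = 1). Of the genes of either organelle, edgeR called 0 and 0 without replicate 1 or 2 of line 5, and without WT replicate 1 it called 13 mitochondria-encoded genes lower and 2 higher. The mitochondria-encoded list lost its camera call without replicate 1 of line 5 (median log2 fold change -0.35) and with the stricter filter (camera, adjusted p = 0.299). Fry, which tests a list against no change and not against the other genes, called neither list. Its adjusted p was 0.362 for mitochondria-encoded and 0.110 for plastid-encoded genes.

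**Figure D3:**
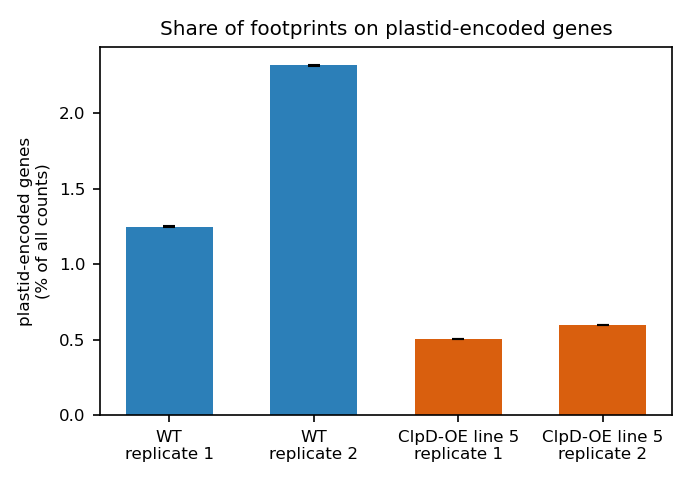
Share of all counts on plastid-encoded genes (y axis, percent) in each library (x axis, WT in blue, ClpD-OE line 5 in orange); error bars are 95% exact binomial intervals, which cover counting error only. The WT libraries lie at 1.25% and 2.32% and the line 5 libraries at 0.503% and 0.597%.

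The remaining lists were not called as groups. Cytosolic translation factors had 0 of 20 tested genes called and 0 adjusted over the list alone; their median log2 fold change was -0.0005, their mean 0.03 and the direction of the test upward (camera, adjusted p = 0.755). The initiation factor gene LSP1 (eIFiso4E) had 0.31 (SE 0.0938). At an unadjusted p under 0.05, 6713 of all genes tested passed edgeR's test. Oxidative and high-light stress genes moved both ways, with 3 of 16 higher and 3 lower, and 4 higher and 3 lower adjusted over the list alone (camera, adjusted p = 0.479). The superoxide dismutases CSD1 (AT1G08830) and CSD2 (AT2G28190) rose 2.57-fold and 2.66-fold and CAT1 by 1.45 on the log2 scale, while the early light-induced genes ELIP1 (AT3G22840) and ELIP2 fell by 3.38 and 3.17 and the photorespiratory catalase CAT2 (AT4G35090) by 1.47. ELIP1 had a log2 fold change of -4.38 without replicate 1 of line 5 and -2.79 without replicate 2, and ELIP2 had 19.7 and 4.90 CPM in these libraries. Of 12 genes of abscisic acid, cold and dehydration, 1 fell, 0 adjusted over the list alone, and 0 rose: RD26 (AT4G27410), with a log2 fold change of -2.53 (SE 0.549), -1.49 without WT replicate 1 and -3.12 without WT replicate 2. The list's median log2 fold change was -0.54 (camera, adjusted p = 0.420), but 0.37 without WT replicate 1 (adjusted p = 0.561) and -1.13 without WT replicate 2 (adjusted p = 5.60e-05). LTI65 (RD29B) had 102 CPM in WT replicate 1 and 9.33 in WT replicate 2, against 4.67 and 5.70 in line 5. Of 8 tested defence genes, 2 fell, also 2 adjusted over the list alone, and 0 rose (camera, adjusted p = 0.549). They were EDS16 (AT1G74710, isochorismate synthase, log2 fold change -0.94, SE 0.144) and the defensin gene PDF1.2 (AT5G44420). PDF1.2 had 71 and 38 counts in WT and 0 and 1 in line 5. Its WT over line 5 ratio was 183 (95% counting interval 32.1 to 7291), and 88.7 without replicate 1 of line 5. Without replicate 2 of line 5 its line 5 count was 0, so no ratio can be given. Of 16 autophagy genes, 1 fell, 0 adjusted over the list alone, and 0 rose (camera, adjusted p = 0.858), namely ATG8F (log2 fold change -0.67, SE 0.137). Seed storage genes had 0 of 5 called and 0 adjusted over the list alone, with a median log2 fold change of -2.05 and CRA1 at 506 and 439 counts in WT against 306 and 58 in line 5 (camera, adjusted p = 0.164). The median was -1.17 without replicate 2 of line 5 and -1.43 without WT replicate 2, where 2 of the 5 lay above 0. That list was called without WT replicate 1 (adjusted p = 0.0170), without replicate 1 of line 5 (0.0151) and without replicate 2 of line 5 (0.0302). Of 4 tested root genes, 1 rose and 1 fell, also 1 and 1 adjusted over the list alone (camera, adjusted p = 0.845): WOX5 (log2 fold change 1.74, SE 0.387, not called without either WT library or by DESeq2) and SCR (-0.92, SE 0.140). Genes of dividing cells had 0 of 7 called and 0 adjusted over the list alone, with PCNA2 at -0.41 (SE 0.179; camera, adjusted p = 0.713). Called without WT replicate 1 were 9 oxidative stress genes lower and 4 higher, and 3 abscisic acid genes lower and 4 higher, and without WT replicate 2 edgeR called 8 abscisic acid genes lower. With replicate 1 or 2 of line 5 left out, edgeR called 1 and 0 of the oxidative stress genes, and none of the named genes of the abscisic acid, defence, autophagy and root lists.

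The 10 largest increases were mostly heat shock genes. ATHSP22.0 (AT4G10250), a small heat shock protein of the endoplasmic reticulum, had 1 and 0 counts in WT and 505 and 415 in line 5 (edgeR, adjusted p = 0.00370). The ratio was 548 over the summed libraries (95% counting interval 98.1 to 21676) and 296 without WT replicate 2. Without WT replicate 1 the WT count was 0, so no ratio can be given. HSP21, HSP23.6-MITO, AT1G53540, HSP17.6A and HSP17.4 (AT3G46230, 31.5-fold) were also among them, with the J-domain protein AT1G56300, which had 11.5 CPM in replicate 1 and 55.8 CPM in replicate 2 of line 5. ACC2 (AT1G36180), a homomeric acetyl-CoA carboxylase predicted to act in the plastid, rose 88.5-fold, from 0.987 and 0.908 CPM to 84.1 and 84.6 CPM (log2 fold change 6.47, SE 0.134). AT1G72660, annotated as a P-loop nucleoside triphosphatase, rose 54.6-fold. AT3G63380, annotated as an E1-E2 type ATPase, had 8 and 2 counts in WT and 336 and 622 in line 5, a ratio of 57.1 (95% counting interval 30.9 to 119), and of 132 without WT replicate 1. Among the 10 largest decreases were the B-box genes BBX30 (AT4G15248) and BBX31 (AT3G21890), which fell by 4.38 (SE 0.563) and 4.07 (SE 0.160) on the log2 scale, and the clock-related MYB genes ASG4 (AT1G01520) and LHY (AT1G01060), which fell by 4.13 (SE 0.262) and 3.70 (SE 0.777). The senescence genes NAP (AT1G69490) and SAG29 (AT5G13170) fell by 4.19 and 3.88. The ubiquitin ligase genes PUB19 (AT1G60190) and AIRP2 (AT5G01520), the stress-induced membrane protein gene TSPO (AT2G47770) and AT1G49450 had log2 fold changes of -3.69, -3.64, -3.99 and -4.08, and WT replicate 1 lay above WT replicate 2 in each of these 4 genes, as in TSPO with 22.5 and 4.58 CPM. Without WT replicate 1 the log2 fold change was 6.84 for AT1G56300, -2.77 for AT1G49450, -2.42 for TSPO and -2.58 for AIRP2. Without WT replicate 2 it was 5.72 for HSP17.4, -4.75 for AT1G49450, -4.71 for TSPO and -4.23 for AIRP2. Leaving out replicate 1 of line 5 gave -5.71 for BBX30, -5.30 for LHY and 6.67 for AT1G56300, and leaving out replicate 2 gave -3.71 for BBX30, -2.97 for LHY and 4.39 for AT1G56300. Of the 10 increases, 8 kept their edgeR call without replicate 1 of line 5 and 6 without replicate 2; of the 10 decreases, 4 and 3 did.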

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

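The crossed block was chosen after seeing the data; all other alternatives were planned. ClpD was called with RLE, upper-quartile scaling, no filter, the stricter filter, the replicate block, DESeq2 and each library left out, with a log2 fold change between 4.19 and 4.27, and 0 of the 2893 genes called took the opposite sign under any setting. The count stayed within 1.5 times of it with RLE (2932), upper-quartile scaling (2981), no filter (3538), the stricter filter (2594), library sizes without organelle genes and ClpD (2909) and DESeq2 (3674). With the replicate block edgeR called 743 genes (286 higher, 457 lower); the samples share only a number, and the deviations of same-numbered libraries correlated at r = -0.117. Under it 42 of the 67 named genes called besides ClpD kept the call and 25 lost it, and the members called were 11 small heat shock proteins, 10 of the HSP70 list, 4 heat shock factors and regulators, 4 mitochondrial stress, 1 endoplasmic reticulum and 2 proteasome genes higher, and 1 photosynthesis, 2 chlorophyll, 47 plastid-encoded and 0 mitochondria-encoded genes lower. The crossed block called 3597 (1530 higher, 2067 lower). An adjusted p under 0.01 left 61 (44 higher, 17 lower), and an added absolute log2 fold change of 1 left 1504 (599 higher, 905 lower). Leaving out 1 library gave 28 to 5101 genes (25 to 2197 higher, 3 to 2904 lower), with the lone library assumed to vary like the other group; fewer libraries were fitted, and why line 5 libraries weighed more was not tested. Of 67 named genes called besides ClpD, 65 kept the call without either WT library, 19 and 16 without replicate 1 or 2 of line 5, and 66 with DESeq2. With an estimated correlation, which leaves little power at 4 libraries, 0 lists were called by limma's camera. Its adjusted p was 0.651 for plastid-encoded and 0.832 for mitochondria-encoded genes. It was 0.443 for the small heat shock protein, HSP70, heat shock factor, proteasome, photosynthesis, chlorophyll, endoplasmic reticulum and mitochondrial stress lists. Fry, which tests a list against no change, called 7 of the 10 lists called by camera with its preset correlation. For these 7 its adjusted p ran from 0.00864 (mitochondrial stress) to 0.0404 (photosynthesis). Fry's adjusted p was 0.0507 for heat shock factors, 0.110 for plastid-encoded and 0.362 for mitochondria-encoded genes. Leaving out 1 library gave camera adjusted p of 0.0197 to 0.0571 for the endoplasmic reticulum list and 0.000134 to 0.118 for mitochondria-encoded genes, which had 0.299 with the stricter filter. Among lists not called, the direction turned with 1 library left out for abscisic acid (5.60e-05 to 0.770), defence (0.517 to 0.971), autophagy (0.637 to 0.896), root (0.637 to 0.971) and dividing cells (0.528 to 0.944), and for root also with no filter (0.832) and the stricter filter (0.525). The log2 fold change of OLEO2 ranged from -1.21 to 0.31, of PYK10 from -0.0505 to 0.30 and of SHR from -0.22 to 0.0487, none of them called; the cause was not tested. At a floor of 3 counts a level under 0.0709 to 0.110 CPM was not detectable at this depth.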

Other observations

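The gene lists here were put together after the data were seen. Their camera p-values were adjusted over these lists alone, so they cannot be set beside those of the 22 planned lists. The tests of the mitochondria-encoded median and of the mitochondrial and plastid percentiles were chosen after the results were seen. Genes of the core hypoxia response were higher in line 5: 9 of 12 tested rose and 0 fell (median log2 fold change 1.52; limma's camera, adjusted p = 2.55e-06; adjusted p = 0.251 with an estimated correlation). AT4G33070, pyruvate decarboxylase 1, rose 8.86-fold, the ethylene receptor gene ETR2 6.18-fold, the plant cysteine oxidase gene AT5G39890 4.81-fold and the alcohol dehydrogenase gene ADH1 2.72-fold. Of 12 tested auxin- and shade-induced genes, 4 rose and 0 fell (median log2 fold change 0.33; camera, adjusted p = 0.000392; adjusted p = 0.342 with an estimated correlation). They were PIL1 (5.57-fold), the auxin synthesis gene YUC8 (3.83-fold), IAA19 (1.91-fold) and HB-2 (1.76-fold), and the median was 0.74 without WT replicate 2. Without replicate 1 or 2 of line 5, edgeR called 0 and 0 genes of either list.

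Single genes singled out after their values were seen were the receptor kinase genes FLS2, which binds bacterial flagellin, and EFR, which binds bacterial elongation factor Tu. FLS2 had 397 and 227 counts in WT and 7338 and 9639 in line 5, a 16.5-fold increase (SE of the log2 fold change 0.280; edgeR, adjusted p = 0.00938), and EFR rose 4.21-fold. ACC1, the cytosolic paralog of ACC2, had a log2 fold change of -0.01 and was not called. Among plastid-encoded genes, 36 of 44 genes of the photosynthesis complexes fell (median log2 fold change -2.03), as did 16 of 27 genes for ribosomal proteins, RNA polymerase, matK and clpP (median -1.39), the medians being -1.41 and -0.99 without WT replicate 2, with matK at 0.06 and rps16 at 0.57, neither of them called. Without replicate 1 or 2 of line 5, 0 and 0 genes of these classes were called. The difference between the classes was not tested.

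LHY, COL2 and ASG4, with higher levels at dawn, fell in line 5, as did 10 of 11 other dawn genes, while EPR1 rose; of 9 dusk genes 1 (ELF4) rose, 8 were not called and 9 lay above 0 (camera, adjusted p = 3.17e-05 for dawn and 0.000681 for dusk; adjusted p = 0.342 with an estimated correlation for both). The dawn median was -1.59 and the dusk median 1.70 (2.46 without WT replicate 2, and 2.86 and 1.02 without replicate 1 or 2 of line 5, where edgeR called 1 and 0 dawn genes lower and 1 and 0 dusk genes higher), in the directions that harvest at another time of day or a shifted clock phase would give. A single wild-type library at another phase is argued against, as the dawn median was -1.44 or lower (-1.75 with the other) whichever WT library was left out. The line 5 replicates differed too, with 12.9 and 2.57 CPM for LHY and 105 and 489 CPM for GRP7. No time of harvest is in the labels. A harvest difference, an effect of ClpD overexpression on the clock or another difference of line 5 may each lie behind the pattern. No test here separates them. Whether any of them also moved the photosynthesis, chlorophyll, or auxin and shade genes was not tested.

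NCED3, an enzyme of abscisic acid synthesis, HB-12, HB-7 and PUB19 fell by 3.47, 3.09, 2.99 and 3.69 on the log2 scale, and of 12 other tested genes 4 fell, 0 rose and 12 lay below 0 (median log2 fold change -1.47; camera, adjusted p = 0.000872; adjusted p = 0.342 with an estimated correlation), of which 0 and 0 were called without replicate 1 or 2 of line 5. WT replicate 1 was higher than WT replicate 2 in each of the 4 named genes, as in NCED3 with 235 and 130 CPM in WT against 17.0 and 15.9 CPM in line 5. For the 12 other genes as a set, that library as the whole cause is argued against. The median of the 12 was still -1.06 without it and -2.03 without WT replicate 2. For LEA14, NAC019 and ABI5 among them it stays open. In these genes WT replicate 2 lay below both line 5 libraries, as in LEA14 with 177 CPM against 198 and 254 CPM. For the planned list of abscisic acid, cold and dehydration genes it stays open, as that median went from -0.54 to 0.37 without WT replicate 1, with 4 genes higher and 3 lower. ClpD overexpression, another difference of line 5 and a difference in growth conditions between the groups stay open, and none of them was tested.

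Plastid-encoded footprints were lower in line 5 across nearly all genes. A few abundant genes as the cause are argued against, since 97.5% of the tested plastid-encoded genes had a log2 fold change below 0. Lower recovery of all organelle footprints cannot be told apart from a change in the plastid: the median was -0.40 for mitochondria-encoded genes, of which 20 of 27 lay below 0, and -1.69 for plastid-encoded genes. Against an equal loss of both, the mitochondrial share was 0.0488% in WT and 0.0459% in line 5 while the plastid share was 3.24-fold lower, and the plastid median lay outside the mitochondrial quartiles of -1.61 and -0.04. An equal loss stays open, as nad6 alone held 5734 of the 12245 mitochondrial counts in WT replicate 1. The lower mitochondrial quartile also lay below the upper plastid quartile of -1.23. An effect of ClpD overexpression, or of another difference of line 5, on plastid translation or mRNA level stays open too and was not tested.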
